A study of Drosophila melanogaster with 6 samples.

How the data were processed

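Total RNA from pools of adult Drosophila melanogaster was measured on 3 2-colour chips of 22575 spots. The samples were 2 replicate pools each of 10, 20 and 40 animals, and each sample was one channel of a chip, with its dye given per the labels. By the series' design text, 16 vials were reared and 5 animals were taken from each, and replicates were made from separate vials. The text gives 2, 5 and 8 vials per replicate of 10, 20 and 40 animals. At 5 animals a vial, 5 vials hold 25 animals and not 20, so the vial number of the 20-animal pools is uncertain. The 2 pools of 40 animals would by these numbers use all 16 vials and all 80 selected animals, while the 6 pools add up to 140. The smaller pools would then share vials, and animals or their RNA, with the 40-animal pools. Pools of different sizes may thus not be independent. Which vials went into which pool is not given in the sources used here. The replicate pools are described as independent, and p-values measure the spread between these pools together with the spread between chips.

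Each sample has a table of spot intensity on a linear scanner scale, deposited by the authors without normalization: the mean, median and mode of the pixels of each spot and of its local background, with a flag, per the file headers. The quantification program is not given in the sources used here. The authors also deposited a table of natural log values, which equalled the natural log of mean spot intensity minus mean background to within 9e-08 at every spot, with no scaling or centring. The medians of its 6 columns, in sample order of 10, 20 and 40 animals, were 5.23, 5.38, 5.73, 4.39, 5.58 and 5.63 on the natural log scale. The flag holds codes whose meaning is not given in the sources used here, and it is the same in both files of a chip, which shows the channels that share a chip. It marked 166, 104 and 123 spots on the 3 chips, and 366 spots on any chip. All spots were kept in the main analysis.

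Mean spot intensity was corrected for mean local background with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3. Values were normalized within each chip by loess and between chips by Aquantile, and one log2 value per channel was taken. Control spots could not be left out, since no spot carries a name. The planned filter for spots well above background needs a flag for that property or a background SD. The flag of the files has codes of unknown meaning, and no background SD was used here, so all 22575 spots were tested. Differences between pool sizes were fitted with lmFit and eBayes on all 6 samples with pool size and dye as terms, two-sided, with Benjamini-Hochberg adjustment over all spots and a threshold of 0.05. The fit had 2 residual degrees of freedom and 6.79 prior degrees of freedom, and the median standard error of a difference was 0.18 on the log2 scale. Chip had been planned as a random block. Its correlation could not be estimated beside the dye term with 6 channels on 3 chips, so the main fit has no chip block. Where the channels of a chip share spot effects, the fit without the block overstates the standard error. With 2 samples against 2, an exact permutation test of one spot could not give a two-sided p below 0.33.

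Replicate spread was computed from the Cy5 minus Cy3 difference of each pool size, less the spot's mean difference over the 3 pool sizes. The variance component of each pool size came from the variances of the 3 pairwise differences of these values, as the squared scaled median absolute deviation. Spot effects shared by a chip also enter the components, by the same amount for each pool size only if they are equally large on the 3 chips. If they are not, they alter the order of the components. Intervals came from 1000 resamples of 300 position blocks of 70 to 77 spots, made of 15 bands of rows and 20 bands of columns. The blocks were resampled as if independent, although neighbouring blocks were alike, so these intervals may be too narrow. Only the intervals for the correlation of block medians between dyes came from resampling larger squares of neighbouring blocks.

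The alternatives fixed before the data were examined were no background correction, plain subtraction with a floor of 1, median scaling, quantile normalization and the upper 60% of spots by mean intensity. Also fixed then were no dye term, chip or replicate number as a block, the authors' values and eBayes with a trend. Leaving out each sample in turn and plain variance for the components were fixed alternatives as well. Those chosen after seeing the data were a correction for position, leaving out Cy3-bright or flagged spots, median pixel intensity, a random chip block without the dye term, an assumed chip correlation of 0.5, and the authors' values centred on channel medians. The position correction subtracted from each channel's deviation from the spot mean its median in the position block. The rule for named genes took the genes with the largest change among named spots, and no spot could be named. The 4 spots printed by number fall outside that rule. The 21 gene lists and their replicate spread were not tested, since no table used here pairs spots with genes.

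The fit was tested on simulated values with the real spots' means, dye effects and fitted spread, 200 changed spots and 20 draws per comparison and fold. A single draw was used at first. It gave 2-fold recovery that differed widely between comparisons of the same design, and was replaced by the mean and range of 20 draws after that was seen. Changes of 4-fold were recovered at 99.1%, 99.2% and 99.1% of changed spots for 20 against 10, 40 against 10 and 40 against 20 animals. Changes of 2-fold were recovered at 2.30%, 1.35% and 1.05%. The simulation has no position effect, and its folds are on the normalized log2 scale, where the offset compresses differences at dim spots. Simulated variance components were recovered to within 0.007 of the value expected with chip effects, equal or unequal.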

Results

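The data were spot intensities from total RNA of adult fruit flies, Drosophila melanogaster, prepared from pools of 10, 20 or 40 animals. Each pool size had 2 replicate pools described as independent, which gave 6 samples. By the stated numbers of vials and animals, pools of different sizes may share animals, which would make them more alike. Each sample was labelled with Cy3 or Cy5, the green and red dyes of a 2-colour chip, and the 6 samples were read as the 6 channels of 3 chips. Every pool size had one replicate in each dye, and every pair of pool sizes shared one chip. Each chip carried 22575 spots in 105 rows and 215 columns. The series asks by its title how many individuals a pool should hold, so the report compares the spot intensities between pool sizes and the spread between replicate pools within each size. The files give no gene name for any spot, so results are given for spots and not for genes, and the 21 gene lists drawn up for adult fly tissues were not tested here.

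The median spot intensity lay between 125.2 scanner units in replicate 2 of the 20-animal pools and 348.5 units in replicate 1 of the 20-animal pools. The other medians were 229.7 and 260.3 units in the 10-animal replicates 1 and 2, and 313.0 and 324.7 units in the 40-animal replicates 1 and 2. Median local background was alike in all 6 samples, from 40.8 to 47.7 units. The median ratio of spot intensity to local background was therefore lowest in replicate 2 of the 20-animal pools, at 2.81, and highest in replicate 1 of the same size, at 8.44. Every spot exceeded its local background in every sample, and the smallest margin was 7.88 units. The range of intensities followed the dye. After subtraction of background, the 95th percentile of spots was 37.9, 31.4 and 78.9 times the 5th percentile in the Cy5 samples of 10, 20 and 40 animals. The same ratio was 7.74, 8.11 and 9.95 in the Cy3 samples. Intensities above 65000 units were found at 2 spots of the 10-animal replicate 1 and 17 spots of the 40-animal replicate 2. The number of chips limits the precision of every value below.

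**Figure D1:**
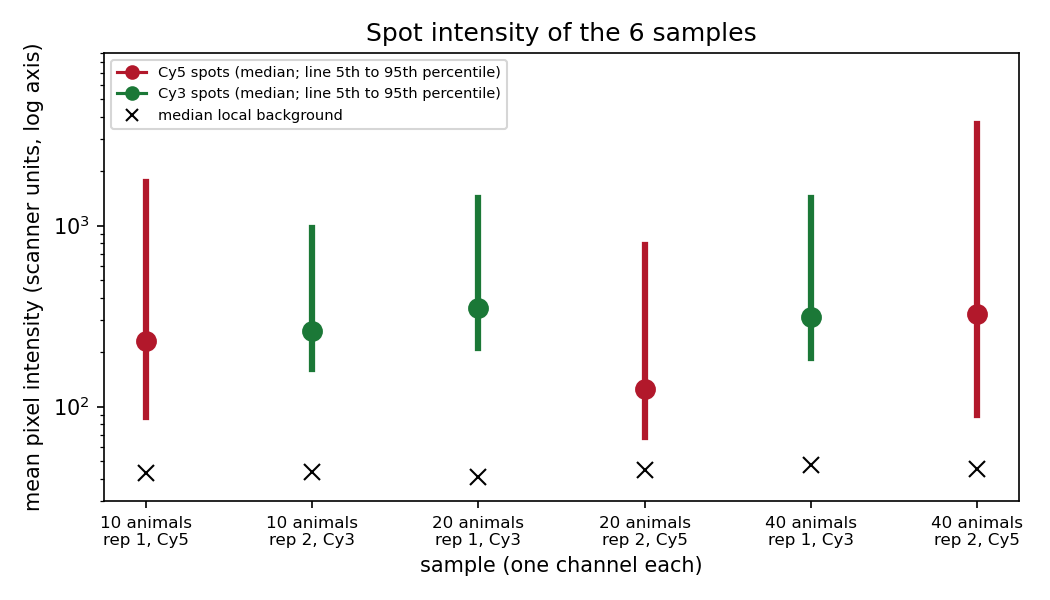
Mean pixel intensity of the spots in each of the 6 samples, in scanner units on a log axis; points are medians over 22575 spots, lines run from the 5th to the 95th percentile, and crosses mark the median local background. The 3 Cy5 samples span a wider range than the 3 Cy3 samples, and the 20-animal replicate 2 has the lowest median, 125.2 units.

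After normalization, samples resembled each other by dye more than by pool size over all spots. Across spots, which are not independent replicates, Pearson's r between samples of the same dye and different pool sizes averaged 0.975, with a range from 0.967 to 0.983 over 6 pairs. The replicates of one pool size, which always carried different dyes, correlated at 0.911 for 10 animals, 0.953 for 20 animals and 0.913 for 40 animals. Pairs that shared neither dye, chip nor pool size correlated at 0.917 to 0.933 over 3 pairs. The 10- and 40-animal replicates lay below that range and the 20-animal replicates above it. Of the sum of squares around the spot means, dye held 63.0% on 1 degree of freedom, pool size 17.2% on 2 and the remainder 19.9% on 2. These values rest in part on 396 spots that were far brighter in Cy3, a set defined after seeing the data. Without them dye held 39.3%, pool size 28.5% and the remainder 32.3%. The 10- and 40-animal replicates then correlated at 0.951 and 0.957, still below all 6 same-dye pairs, whose lowest r was 0.967. The 20-animal replicates correlated at 0.976, within the range of the same-dye pairs, and the 20-animal replicate 2 and 40-animal replicate 1, which shared a chip, at 0.988, above all of them. Dye was a term in every main fit and was subtracted from every replicate difference.

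**Figure D2:**
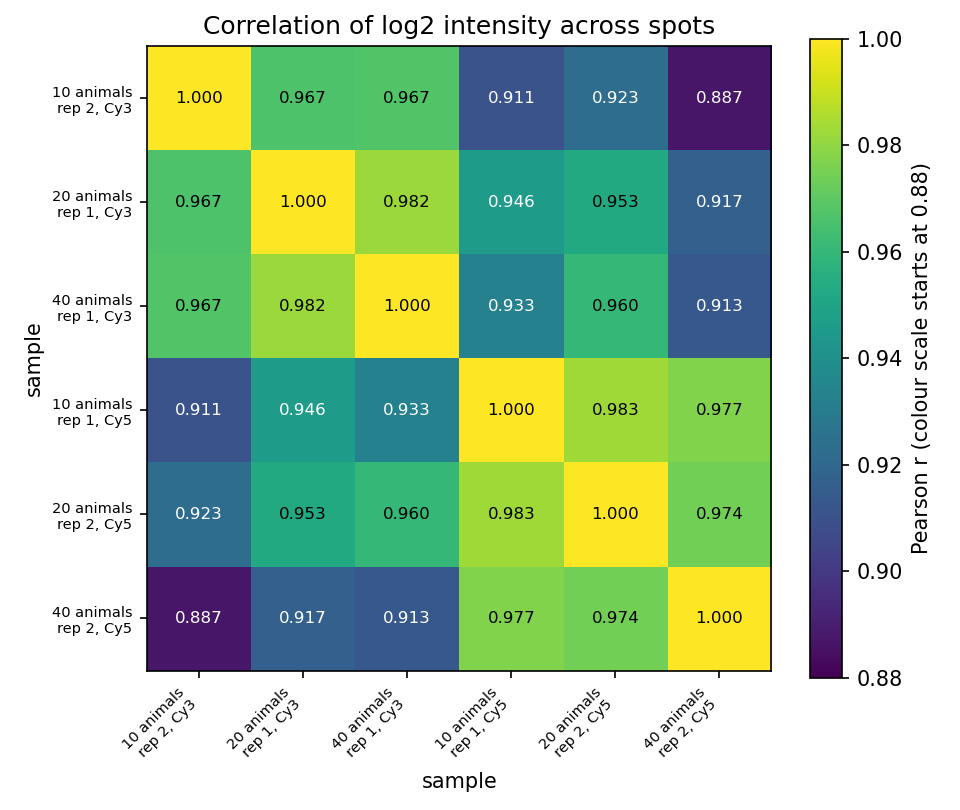
Pearson's r of normalized log2 intensity across 22575 spots for every pair of the 6 samples, ordered by dye; the colour scale starts at 0.88. Pairs of the same dye lie between 0.967 and 0.983, above the 0.911 and 0.913 of the 10- and 40-animal replicate pairs and the 0.953 of the 20-animal pair.

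The comparison of 20-animal with 10-animal pools asked which spots differ in intensity when the pool is doubled. No spot passed an adjusted p of 0.05 in the limma fit, in either direction. The smallest adjusted p was 1, and 438 of 22575 spots had an unadjusted p under 0.05, against 1129 expected by chance alone. Leaving out any one sample moved that count: it was 2227 and 194 without replicates 1 and 2 of the 10-animal pools, 1002 and 1505 without those of the 20-animal pools, and 894 without either of the 40-animal pools. After correction for position on the chip, an alternative chosen after seeing the data, it was 235. The median absolute difference was 0.12 on the log2 scale and 95% of spots differed by less than 0.41. The 95% interval of the difference lay inside a 2-fold change in either direction for 21818 spots, or 96.6%. The typical half-width of that interval was 0.41 on the log2 scale. In the median-scaled values, 21 spots were called, 2 higher and 19 lower in the 20-animal pools. The fit of those values used one variance for all spots, since its prior degrees of freedom were infinite, and so gave no weight to the spread of the single spot. The fits that left out one sample called from 3 to 42 spots, the most without replicate 1 of the 20-animal pools.

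The comparison of 40-animal with 10-animal pools set the largest pools against the smallest. Again no spot passed an adjusted p of 0.05 in the limma fit, and the smallest adjusted p was 0.811. The number of spots with an unadjusted p under 0.05 was 1385, against 1129 expected by chance. It was 746 without replicate 2 of the 10-animal pools and 2039 without replicate 2 of the 40-animal pools. The median absolute difference was 0.15 on the log2 scale and 95% of spots differed by less than 0.47. For 21744 spots, or 96.3%, the 95% interval lay inside a 2-fold change, with the same limit from the offset at dim spots. In the median-scaled values 39 spots were called, none higher and 39 lower in the 40-animal pools. After correction for position the count of spots with an unadjusted p under 0.05 was 590. The fits that left out one sample called from 0 to 28 spots.

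The spots with the smallest unadjusted p in the comparison of 40 with 10 animals are given as examples that did not pass in the main values, and were chosen after their values were seen. Spot_20903 and spot_18779 had the smallest p among the spots with higher values in the 40-animal pools. Spot_20903 measured 7.61 ± 0.51 in the 40-animal pools and 6.73 ± 0.77 in the 10-animal pools on the log2 scale (mean ± SD, n = 2 each), with an adjusted p of 0.811 in limma. The difference was 0.88 with a standard error of 0.17, and the replicates of the 2 pool sizes overlapped. These SDs include the difference between the dyes, which the fit removes. Spot_18779 measured 7.50 ± 0.52 and 6.64 ± 0.44, a difference of 0.86. Both lay in blocks of the chip where the median spot was also higher in the 40-animal pools, by 0.41 and 0.35. Corrected for position, their differences were 0.51 and 0.50. Spot_5507 and spot_5451 had the smallest p among the spots with lower values. Both lay in row 26 of the chip, within rows 23 to 27, which held 142 spots that were brighter in Cy3. Their own dye effects were -1.35 and -1.0, against a median absolute effect of 0.16 over all spots. Spot_5507 measured 6.02 ± 0.42 in the 40-animal pools and 7.34 ± 1.25 in the 10-animal pools, a difference of -1.32. Spot_5451 measured 7.02 ± 1.17 and 8.33 ± 0.15, also a difference of -1.32. The adjusted p in limma was 0.811 for all 4 spots. In the median-scaled values, with one variance for all spots, spot_5507 and spot_5451 passed, with adjusted p of 0.00182 and 0.00449 in limma. Spot_5507 also passed without replicate 2 of the 40-animal pools, at an adjusted p of 0.00472 in limma, and its difference was -0.75 without replicate 1 of that size. Spot_5451 passed without replicate 1 of the 40-animal pools, at 0.0167, and its difference was -0.83 without replicate 2 of that size, -0.73 without replicate 1 of the 10-animal pools and -0.61 with median pixel intensity. With no background correction the differences were 0.56 for spot_20903, 0.49 for spot_18779 and -0.87 for spot_5507.

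The comparison of 40-animal with 20-animal pools had the smallest median absolute difference in the main values. By count of spots with an unadjusted p under 0.05 in limma, it was not the lowest after correction for position. The corrected counts were 235 for 20 against 10, 468 for 40 against 20 and 590 for 40 against 10. No spot passed an adjusted p of 0.05 in the limma fit, the smallest adjusted p was 1, and 336 spots had an unadjusted p under 0.05. That count was 1384 without replicate 1 of the 40-animal pools, 1110 and 1037 without replicates 1 and 2 of the 20-animal pools, 1030 in the median-scaled values and 468 after correction for position. The median absolute difference was 0.11 on the log2 scale, and 95% of spots differed by less than 0.355. The 95% interval lay inside a 2-fold change for 22066 spots, or 97.7%, again with the limit from the offset at dim spots. The median-scaled values gave 6 calls, all lower in the 40-animal pools. The F-test over the 3 pool sizes also called no spot, with 615 spots at an unadjusted p under 0.05, a count between 459 and 1780 when one sample was left out, and 48 calls in the median-scaled values. The fits that left out one sample called from 0 to 39 spots for 40 against 20 animals and from 2 to 39 in the F-test. In simulated data with the spread of the real spots, 4-fold changes at 200 spots were called at 99.1% of the changed spots in this comparison, as the mean of 20 draws. Changes of 2-fold were called at 1.05% of them, with a range from 0 to 21% over the draws. With 200 changed spots and neither position nor chip effects, simulated differences of 2-fold were therefore mostly not called. Of the unchanged simulated spots, 5.03% had an unadjusted p under 0.05 in limma, while the real fit gave 336 spots against 1129 expected. The simulation thus differs from the data, and other numbers of changed spots were not simulated. The absence of calls alone does not rule out 2-fold differences.

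The differences were set against themselves in the other dye, since each comparison can be made once among the Cy5 samples and once among the Cy3 samples, with no sample in common. Across spots the Cy5 and Cy3 estimates correlated at -0.105 for 20 against 10 animals, 0.0756 for 40 against 10 and -0.237 for 40 against 20. After correction for position these values were -0.286, -0.00944 and -0.184. The estimates had the same sign at 45.3%, 54.6% and 43.5% of spots. No spot exceeded 2-fold in the same direction in both dyes, while 11, 7 and 14 spots exceeded it in opposite directions. The Cy5 and Cy3 estimates of a comparison share one chip with opposite sign, which lowers these correlations when the channels of a chip vary together.

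The replicate spread asked whether larger pools gave replicates that lie closer together. The replicate difference of each size was corrected for dye by subtracting the spot's mean difference over the 3 sizes. The median absolute corrected log2 difference was 0.155 for 10 animals, 0.151 for 20 animals and 0.148 for 40 animals. Intervals from resampling the position blocks of the chip ran from 0.149 to 0.162, from 0.146 to 0.156 and from 0.140 to 0.155. The 3 corrected differences of a spot sum to 0, since their mean was subtracted. The 3 medians are therefore not separate measurements and are drawn together by construction. Each corrected difference also holds part of the differences of the other sizes, so it is not that of its own size alone. Corrected differences beyond 2-fold were found at 71, 69 and 54 spots. The variance component of the replicate difference was 0.0748 for 10 animals, 0.0876 for 20 animals and 0.0543 for 40 animals. Their square roots were 0.273, 0.296 and 0.233 on the log2 scale. The component of the 10-animal pools was 1.38 times that of the 40-animal pools, with an interval from 1.11 to 1.71, and 0.853 times that of the 20-animal pools, with an interval from 0.688 to 1.10. After correction for position these ratios were 1.04, from 0.899 to 1.18, and 0.592, from 0.530 to 0.664. These intervals cover the choice of spots only, and they may be too narrow, since neighbouring blocks were resampled as if independent. With plain variance across spots in place of the scaled median absolute deviation, the components lay closer together, at 0.102, 0.11 and 0.0936 for 10, 20 and 40 animals. Each pool size had 1 pair of replicate pools, so no test between pool sizes was made. The order of the 3 sizes changed with the processing: with quantile normalization the components were 0.113, 0.0677 and 0.0478, and with plain background subtraction 0.0622, 0.0647 and 0.0697. The 10-animal component was the smallest in the last of these, without background correction (0.0364, 0.0496 and 0.0461), with median scaling (0.00608, 0.490 and 0.139) and in the authors' values (0.0123, 0.140 and 0.155).

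**Figure D3:**
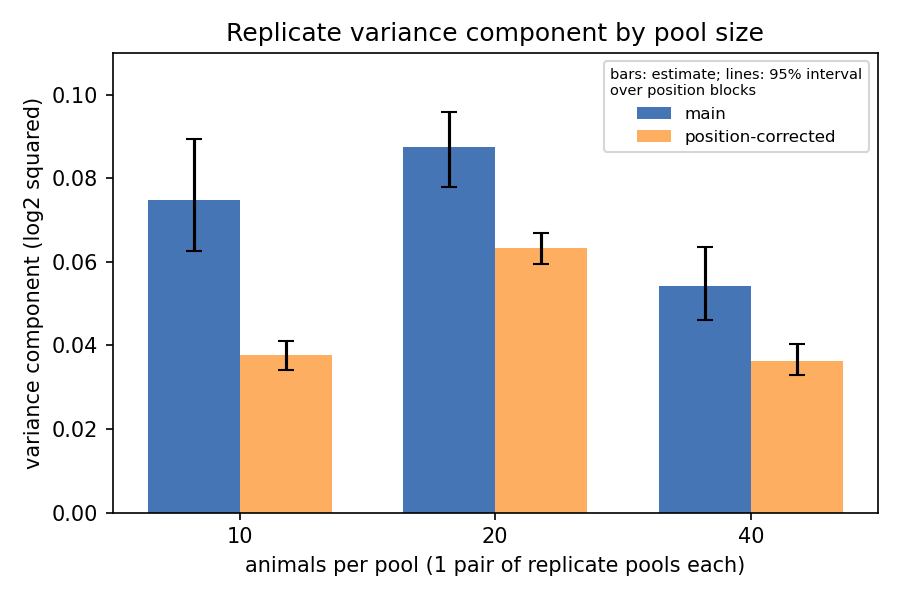
Variance component of the replicate difference, in squared log2 units, for pools of 10, 20 and 40 animals, each from 1 pair of replicate pools; bars start at 0 and lines are 95% intervals over position blocks. The 20-animal pools have the highest component in the main values, 0.0876, and after correction for position on the chip, 0.0634.

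The median corrected replicate difference was lowest in the brightest spots in all 3 pool sizes. Spots were ranked by mean intensity into 5 equal bins, from dim to bright. The median absolute corrected replicate difference in bin 1 was 0.157, 0.159 and 0.155 for 10, 20 and 40 animals. It was 0.175, 0.169 and 0.157 in bin 2, and 0.133, 0.136 and 0.124 in bin 5. The variance component of the 40-animal pools was no lower in bin 5, at 0.0466, than in bin 2, at 0.0457. The median absolute dye effect was 0.22 on the log2 scale in bin 1, 0.25 in bin 2 and 0.09 in bin 5.

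Differences between pool sizes varied with the position of a spot on the chip. When the chip was divided into 300 blocks, the blocks held 52.3% of the variance of the difference between 20 and 10 animals, 50% for 40 against 10 and 16.6% for 40 against 20. A share of 1.32% would be found with no effect of position. Spots beside each other in a row correlated in these differences at 0.607, 0.557 and 0.217, whereas their mean intensities correlated at 0.0106. The samples were not equally uneven. Of the variance of a sample's deviation from the spot mean, blocks held 35% in the 10-animal replicate 2 and 6.03% in the 10-animal replicate 1. In the 20- and 40-animal samples they held from 11.7% to 23.1%. The 10-animal replicate 2 enters both comparisons with the larger shares. In the corner of the last rows and first columns, 1378 spots had a median difference of 0.21 for 20 against 10 animals and 0.34 for 40 against 10. In the corner of the last rows and last columns the medians were -0.21 and -0.21.

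**Figure D4:**
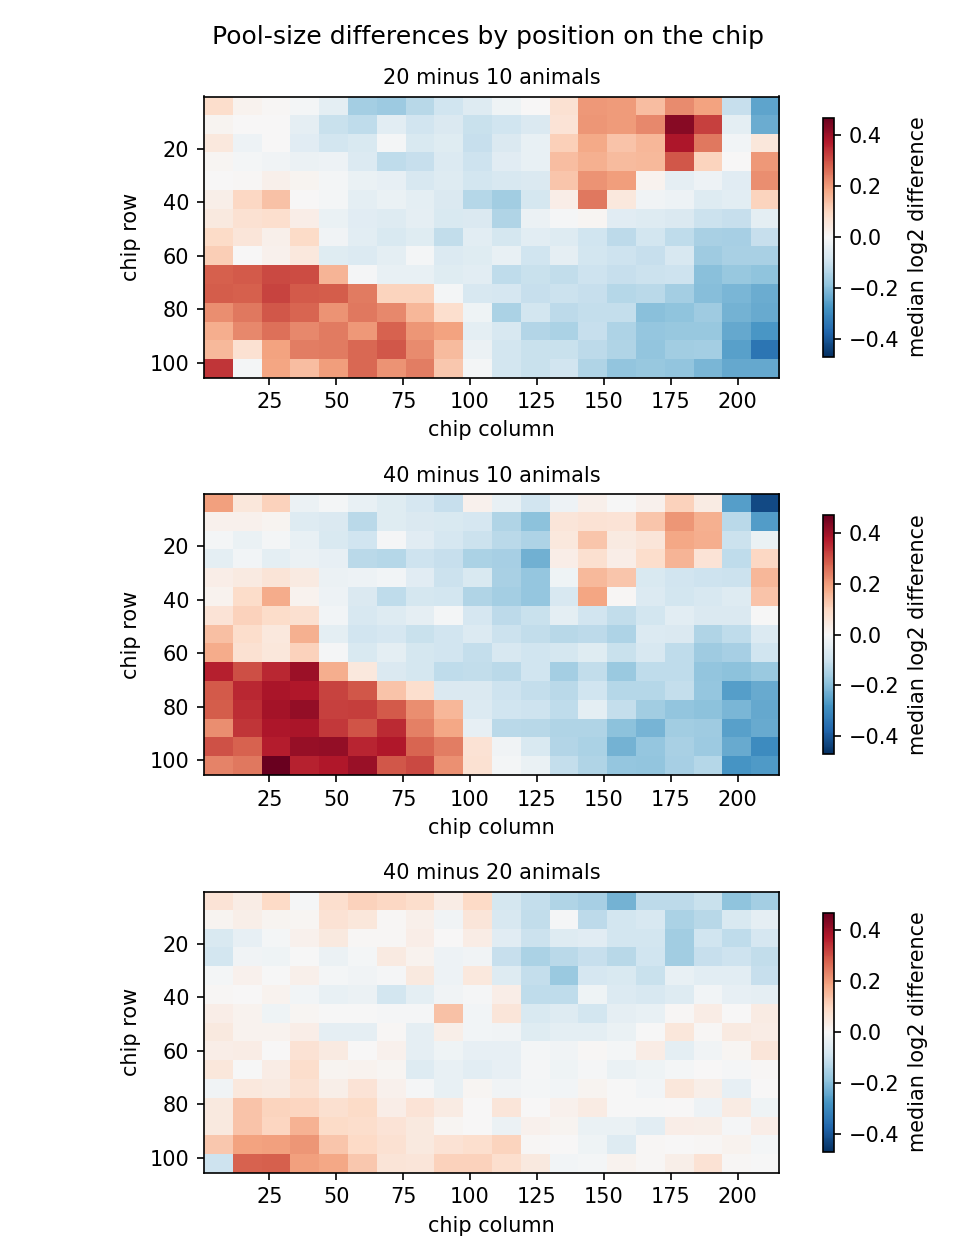
Median log2 difference in spot intensity between pool sizes in 300 blocks of the chip, drawn by chip row and column; red is higher and blue lower in the larger pool. In both comparisons with the 10-animal pools, the corner of the last rows and first columns is higher, with medians of 0.21 and 0.34, and the corner of the last rows and last columns lower, at -0.21. Both comparisons use the same 10-animal samples and so do not repeat each other independently.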

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

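No spot was called in any of the 3 comparisons or the F-test, in limma at an adjusted p of 0.05, without background correction, with plain subtraction, quantile normalization, the upper 60% of spots, no dye term, chip as a fixed block, the authors' values or eBayes with a trend. The same held for the alternatives chosen after seeing the data: position correction, leaving out Cy3-bright spots, both together, leaving out flagged spots, median pixel intensity, the authors' values centred on channel medians, a random chip block without dye and an assumed chip correlation. That last fit gave 4919 spots at an unadjusted p under 0.05 for 40 against 10 animals, against 1385 in the main fit, and a smallest adjusted p of 0.111. For the same comparison, chip as a fixed block gave 26 such spots, the authors' values 11 and a random chip block without dye 1492. The chip correlation estimated without a dye term, so with the dye effect left in, was -0.651. The channels of a chip always carry different dyes, which lowers this estimate, so it cannot judge the assumed 0.5. Median scaling called 21 spots for 20 against 10, 39 for 40 against 10, 6 for 40 against 20 and 48 in the F-test, with infinite prior degrees of freedom, so that one variance served all spots. Whether this caused the calls was not tested. Leaving out one sample, with the lone sample of its pool size assumed to vary like the other groups and 1 residual degree of freedom, called from 3 to 42 spots for 20 against 10, from 0 to 28 for 40 against 10, from 0 to 39 for 40 against 20 and from 2 to 39 in the F-test. The highest counts came without the 20-animal replicate 1 (42, and 39 in the F-test), the 40-animal replicate 2 (28) and the 20-animal replicate 2 (39). The cause was not tested.

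Replicate number as a block called 0 spots in every comparison, with or without the dye term. The numbers share no stated batch: the replicate 1 minus replicate 2 differences correlated across spots at -0.622, -0.708 and 0.627 between pool sizes, as the dyes are placed.

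The replicate spread left its interval over position blocks, which may be too narrow, in most settings. For 10, 20 and 40 animals it was 0.113, 0.117 and 0.121 without background correction, 0.194, 0.321 and 0.234 with median scaling, and 0.262, 0.172 and 0.240 without subtraction of the dye effect. For 10 and 20 animals it was 0.142 and 0.139 with plain subtraction, 0.175 and 0.142 with quantile normalization, and 0.148 and 0.143 in the upper 60% of spots. The cause was not tested. In the authors' values it was 0.460, 1.21 and 0.734, and in the same values centred on channel medians 0.135, 0.190 and 0.198, so most of that increase came from the missing scaling. Position correction gave 0.112, 0.127 and 0.115, and 0.111, 0.124 and 0.113 without Cy3-bright spots. The settings without Cy3-bright spots alone, without flagged spots and with median pixel intensity stayed within the intervals. Among the 14 settings, the smallest spread fell to each of the 3 sizes at least once. Median signal over background was lowest, at 2.81, in the 20-animal replicate 2, and its effect on the spread was not tested. The filter with no exclusions and the fit without a chip block equal the main setting and were not run again. The 2 results on gene lists were not run.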

Other observations

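The tests in this part were chosen after the patterns were seen. The bounds for the correlation of block medians between dyes were set before that correlation was computed, and those of all other tests after their results were seen.

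Differences between pool sizes varied with position on the chip. Unevenness across the chips is a candidate explanation. It needs differences that hold no pool-size contrast to vary with position too, and in the Cy5 minus Cy3 difference within a pool size the position blocks held at least 15.6% of the variance, against 1.32% with no position effect. A pool-size effect as the whole cause would repeat in both dyes. The block medians of the Cy5 and Cy3 estimates correlated at 0.207 for 40 against 10 animals, with an interval from -0.198 to 0.485, and at -0.450 for 40 against 20, from -0.652 to -0.215, both below the 0.5 set in advance. For 20 against 10 animals the value was 0.218, with an interval from -0.0797 to 0.504 that reaches the bound, so this test cannot decide there. In the Cy5 minus Cy3 difference within the 10- and 20-animal pools, blocks held 31.8% and 31.6% of the variance without Cy3-bright spots. With the dye effect subtracted, over all spots, they held 37.7% and 23.6%. A pool-size effect would act on both replicates alike, so the differences within these sizes varied with position for another reason. The uncorrected values may hold a dye effect that varies with position, and the corrected ones hold part of the other sizes' differences. They therefore do not decide whether pool size is the whole cause for 20 against 10 animals. A pool-size effect as part of the cause stays open in all 3 comparisons.

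Samples resembled others of the same dye more than the other replicate of their pool size. A grid of spots was far brighter in Cy3: 246 spots in 8 rows, spaced 7 columns apart, had a median Cy5 minus Cy3 difference of -3.28 on the log2 scale, and 396 spots lay below -1.5. These spots are not the whole cause for the 10- and 40-animal pairs: without them the Cy5 minus Cy3 differences of those sizes still correlated at 0.438, with an interval from 0.402 to 0.474. Without them the 20-animal replicates correlated at 0.976, within the same-dye range from 0.967 to 0.983, so that pair no longer stood below the same-dye pairs. Its Cy5 minus Cy3 differences still correlated at 0.277 with those of 10 animals and 0.245 with those of 40. The Cy3-bright spots are therefore not the whole of its dye effect either. Replicate number in place of dye would turn the correlations with the 10-animal pools negative, and the lower of them was 0.277. A dye effect of each spot that repeats across chips remains a candidate explanation, with a lowest correlation of 0.271 after position correction and without those spots. Dye was crossed with pool size, so a pool-size effect would not make samples of one dye alike. Whether samples of one dye share vials is not given in the sources used here, and no biological explanation was tested.

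Replicate variance did not fall steadily with pool size in the main or position-corrected values, but did with quantile normalization, with components of 0.113, 0.0677 and 0.0478. It rose steadily with plain background subtraction, at 0.0622, 0.0647 and 0.0697, and in the authors' values, at 0.0123, 0.140 and 0.155. A variance between pools that falls in proportion to the number of animals would make the 10-animal component exceed the 20-animal component. This holds only if technical spread and chip effects are alike for all sizes. The ratio was 0.853, with an interval from 0.688 to 1.10. After position correction it was 0.592, from 0.530 to 0.664. The design has 1 pair of pools per size, and the order changes with the normalization. This explanation, chance between pools and unequal technical spread or chip effects therefore cannot be told apart. Unevenness across the chips may form part of the spread, since correction for position lowered the components by 49.7%, 27.6% and 33.1% for 10, 20 and 40 animals. After the correction the components were 0.0376, 0.0634 and 0.0363.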
